A study of Mus musculus with 144 samples.

How the data were processed

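Single cells from the cochlea of mice at postnatal day 15 (C3HeB/FeJ background) were labelled by the submitters as outer hair cells (OHC, 61 cells), inner hair cells (IHC, 34 cells) or Deiters' cells (37 cells), and 12 further OHCs were sequenced with Nanopore reads. OHCs and IHCs are the sensory cells of the organ of Corti, and Deiters' cells are the supporting cells beneath the OHCs. The tissue was dissociated with collagenase, and each cell was picked with a glass micropipette, washed and picked again before cDNA was made with Smart-seq2, a full-length method without molecular identifiers.

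The deposited tables per cell hold estimated counts and TPM (transcripts per 1000000) for each Ensembl transcript, per the file headers. kallisto, STAR, SAMtools and the mm10 build are named in the submitters' processing notes without versions or roles, and the transcript set is not stated. The column names of the tables are those of kallisto's abundance table. The deposited gene matrix has 47752 gene symbols and 132 cells, and no header gives its unit. Its values are whole numbers that follow the estimated counts summed by gene, so it was read as rounded estimated counts of the authors. Among the symbols, 27 had the form of dates and held 0.230% of all counts. These and 2 duplicated symbols were left out of the gene comparisons. The Nanopore gene table was deposited as reads per gene per 10000 reads in each cell, and the authors' Nanopore isoform table as reads per isoform per 10000 reads. Isoform values were turned into reads by taking the smallest positive value of each cell as 1 read, and 100% of the positive values were then whole numbers within 0.01.

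Gene values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Each cell's counts were divided by its total and multiplied by 1000000 (CPM). The mean over cells, with each cell weighted equally, was taken for each type, and 2 types were compared as the log2 ratio of their means after adding 1 CPM to each. All cells were kept. Genes with a mean of at least 1 CPM in a type numbered 14581. Coordinates are those of GENCODE M21 on GRCm38 (mm10). Of 98492 transcripts, 97116 (98.6%) had a GENCODE M21 entry, and those without one held 0.588% of the counts.

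Each sample is 1 cell and no animal, dissection day or sequencing batch is named, so cells cannot be assigned to animals and each cell type counts as 1 sample. No test across cells was therefore made, and no p-value or count of changed genes is given. No paired analysis was possible because the labels name no animal shared between groups. Every SD is the spread between the cells of a type and describes these libraries alone. Shares of cells carry exact Clopper-Pearson intervals at 95%, and a share of 0 carries the limit that 3 counts allow. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules and cells of 1 animal are not independent either.

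The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is described as made after the data were seen. The rule took, for each comparison and direction, the 12 genes with the largest log2 ratio among those with a mean of at least 20 CPM and a count in at least 50% of cells in the higher type. Clone, ribosomal and mitochondrial symbols were left out of these lead genes. It also took up to 4 members of each list with the largest ratios, and 14 marker genes in every comparison: Slc26a5, Ocm, Ikzf2, Slc17a8, Otof, Tbx2, Myo7a, Pou4f3, Tmc1, Gjb2, Gjb6, Sox2, Prox1 and Fgfr3.

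The 27 lists covered hair cell, OHC, IHC, Deiters' cell, pillar cell and supporting cell markers. They covered mechanotransduction and stereocilia, the ribbon synapse, the efferent synapse, potassium channels, gap junctions with ion and glutamate homeostasis, Notch signalling, extracellular and tectorial matrix, and calcium buffering and transport. Hereditary deafness genes, immediate early and stress genes, cytosolic ribosome, mitochondrially encoded and nuclear oxidative phosphorylation genes were further lists. Other cells that a pipette could carry had lists of their own, namely neuron, glia and myelin, blood, immune, endothelial, fibroblast, stria vascularis and bone or cartilage markers. A list's value is the median log2 ratio of its members with at least 1 CPM in a type. Its percentile is the place of that median among 10000 random lists of the same size, matched on mean expression in 20 bins (seed 15), and describes these libraries alone. A list's score in a cell is the mean of log2(CPM + 1) over its members.

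The share of cells with a gene was counted after each cell was thinned at random to 100000 counts, which left out 7 shallower cells. Labels were checked by the z-scaled list scores of each cell, and no cell was moved. For 132 of 140 fixed deafness genes found in the matrix, a mean of at least 10 CPM was counted as expressed. Results for some genes are not reported here. Transcript shares used estimated counts summed by type, for deafness genes with at least 200 counts, at least 10 cells with 20 counts or more, and more than 1 transcript at 10% or more. The 8 transcripts with the largest difference were named per comparison. Assignment of reads between similar transcripts by the quantifier carries an error that no interval covers. Nanopore and Illumina tables were compared by Spearman's rho across genes, in which genes are not independent replicates.

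The calculation was tested on simulated data in which 50 genes per fold, all with at least 20 CPM, were raised between types. The simulated spread between cells had an SD equal to the mean, so genes with a larger spread were not tested. Before recovery was scored, the median ratio of the unchanged genes was subtracted, which was not done in the comparisons of the real cells. For 2-, 4-, 8- and 16-fold changes the median recovered log2 ratio was 1.00, 1.94, 3.06 and 4.01 in IHC against OHC, and 98 to 100% of genes in all 3 comparisons lay within 1 log2 of the simulated change. Alternatives covered averaging, scaling, the pseudocount, gene filters, thinning, the source of counts and the cells kept, with each cell also left out in turn. Values without the 5 shallowest IHC libraries, without 4 IHC libraries with high immune scores and without OHC_139 were added after the data were seen. Scaling by size factors from 126 genes with a count in all cells moved the median of all genes by 1.12 log2 in Deiters' cells against OHC and by 1.21 in Deiters' cells against IHC. The mean of logs moved it by 0.243 in IHC against OHC and by 0.149 in Deiters' cells against OHC, the median over cells by 0.117 and 0.116, and TPM by -0.155 in IHC against OHC.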

Results

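The data are 132 Illumina libraries of single cochlear cells at postnatal day 15, with 61 outer hair cells (OHC), 34 inner hair cells (IHC) and 37 Deiters' cells, and 12 Nanopore libraries of further OHCs. Each library is 1 cell, named by its label, such as OHC_139. Total gene counts ran from 83556 to 10766239 in OHCs (median 3582581), from 11187 to 11871956 in IHCs (median 3031480.5) and from 483983 to 8299319 in Deiters' cells (median 4274087). The median cell had a count for 8632 genes in OHCs, 8064.5 in IHCs and 8912 in Deiters' cells. Fewer than 100000 counts were present in 1 OHC and 6 IHCs. The 10 most abundant genes took a median of 6.11% of the counts of an OHC, 10.6% of an IHC and 18.7% of a Deiters' cell. Unless another n is given, levels are mean CPM ± SD between cells over these 61, 34 and 37 cells, ratios are log2 ratios of the means, and no difference was tested.

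The marker genes followed the labels in most cells, with 1 exception among the OHCs and a second signature in most IHCs. The hair-cell list had a mean score of 7.69 ± 1.06 in OHCs, 6.76 ± 0.92 in IHCs and 2.85 ± 0.61 in Deiters' cells. The supporting-cell list scored 1.26 ± 0.49, 3.48 ± 1.71 and 3.96 ± 0.66 in the same order. By z-scaled scores, 60 of 61 OHCs and 37 of 37 Deiters' cells fell with their label, but only 13 of 34 IHCs did. The other 21 IHCs scored higher on the scaled supporting-cell list than on the scaled hair-cell list, while all 34 scored higher on scaled IHC than on scaled OHC markers. Without scaling, 61 OHCs, 30 IHCs and 32 Deiters' cells fell with their label. The exception among the OHCs, OHC_139, had a hair-cell score of 1.74 and a blood score of 6.20, with 455739 counts and 2196 genes.

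**Figure D1:**
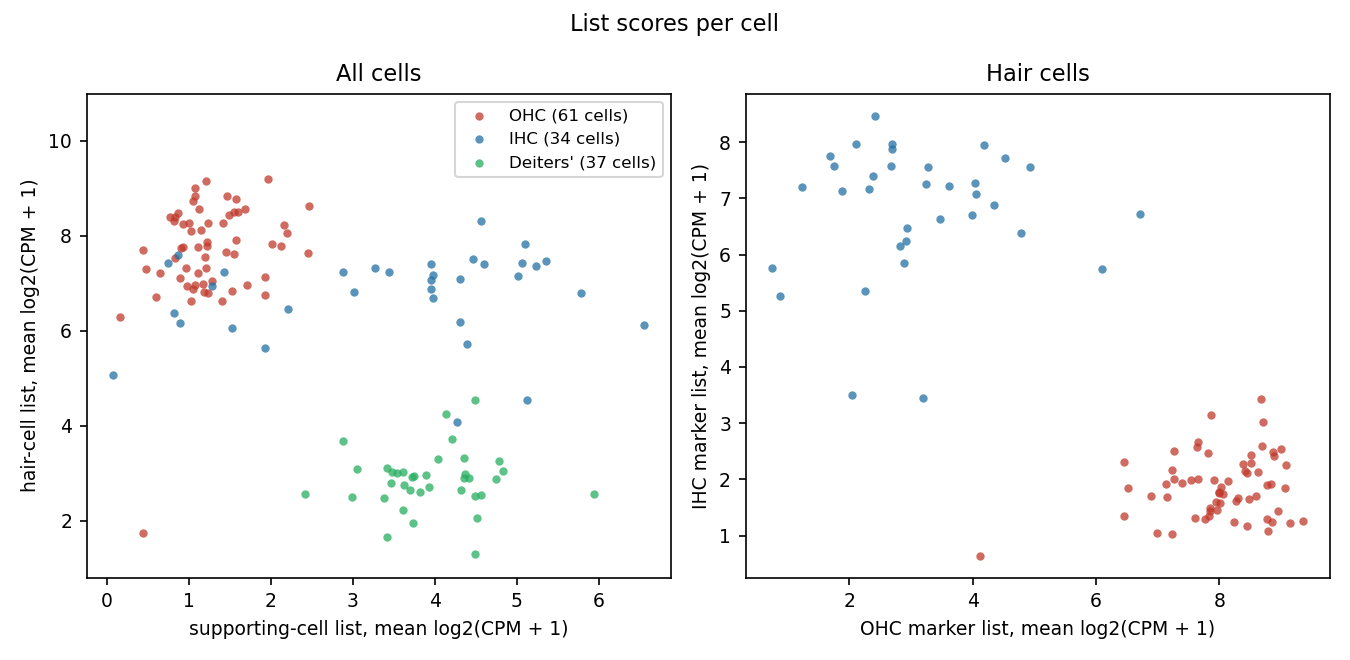
Each point is 1 cell, placed on the left by its supporting-cell and hair-cell list scores (mean log2(CPM + 1)) and on the right, for hair cells alone, by its OHC and IHC marker scores. OHCs and Deiters' cells form separate groups on the left with OHC_139 apart, 24 of 34 IHCs lie to the right of the highest OHC supporting-cell score of 2.46, and on the right OHCs lie at low and IHCs at high IHC marker scores (means 1.87 and 6.79).

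The comparison of IHCs with OHCs asks which genes separate the sensory cell that signals to the auditory nerve from the one that amplifies sound by changing its length. OHCs had far more Slc26a5, which encodes the motor protein prestin, and Ocm, which encodes the calcium-binding protein oncomodulin. IHCs had far more Otof, whose product otoferlin is needed for transmitter release, and Slc17a8, which encodes the vesicular glutamate transporter of IHCs. Slc26a5 (chromosome 5, 21810655 to 21865604) had 3879 ± 1849 CPM in OHCs and 42.4 ± 170.7 in IHCs, a ratio of -6.48, or -8.02 without IHC_240. Ocm had 7979 ± 3831 in OHCs against 273 ± 580 in IHCs (ratio -4.87). Otof (chromosome 5, 30367062 to 30461932) had 3754 ± 2111 in IHCs against 97.7 ± 200 in OHCs (ratio 5.25), and Slc17a8 (chromosome 10, 89574020 to 89621253) had 202.5 ± 283.2 against 1.48 ± 1.55 (ratio 6.36). The OHC marker list was higher in OHCs for 9 of 10 members (median -3.71, percentile 0), and the IHC marker list was higher in IHCs for 11 of 11 (median 5.45, percentile 100). The scores of these lists differed by more than the SD between cells, at 8.01 ± 0.87 in OHCs and 3.11 ± 1.35 in IHCs for OHC markers and at 1.87 ± 0.56 and 6.79 ± 1.16 for IHC markers.

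**Figure D2:**
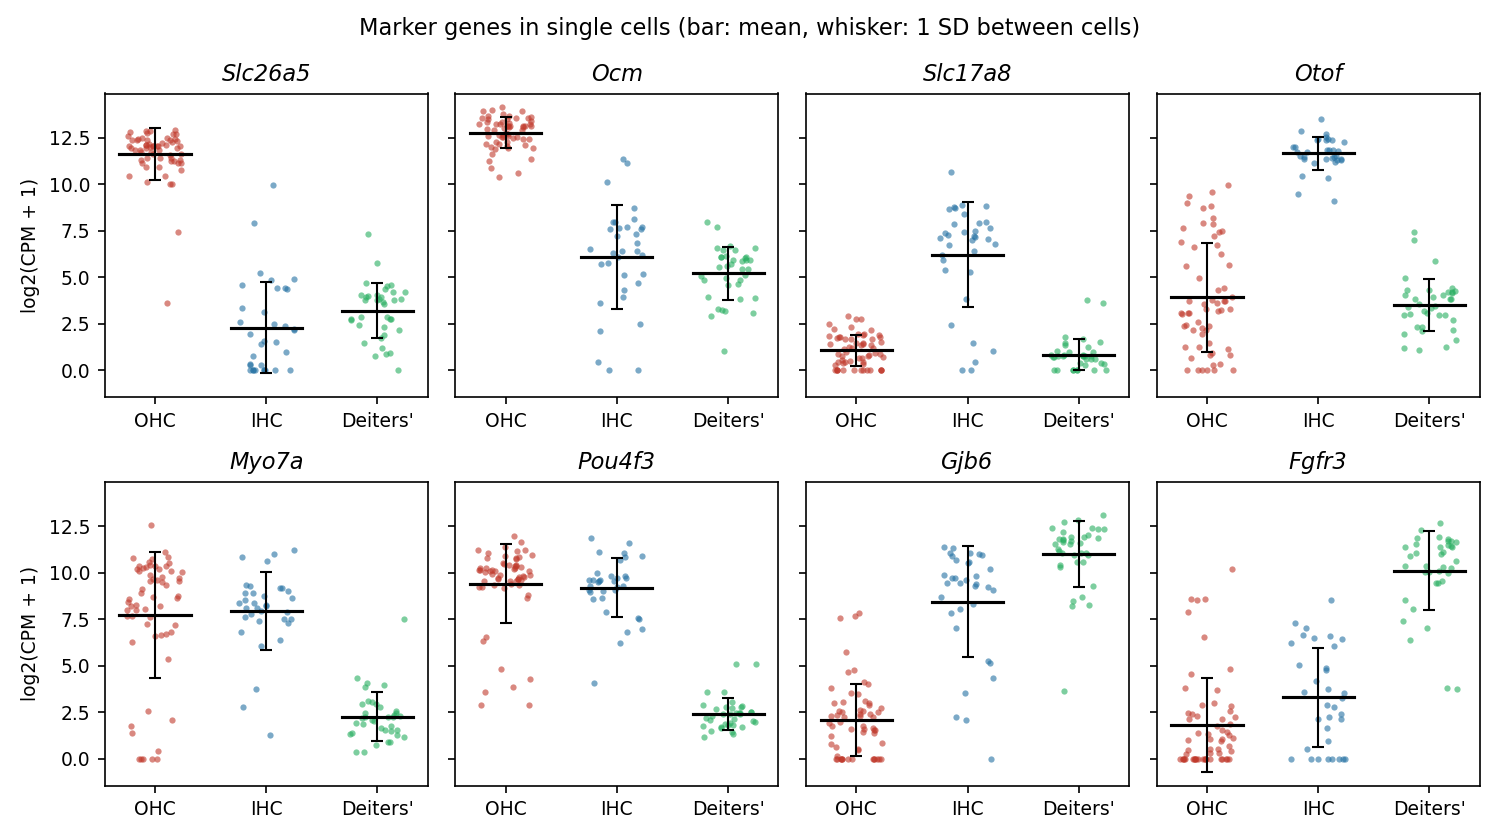
Each point is the log2(CPM + 1) of 1 cell for 8 marker genes in OHCs, IHCs and Deiters' cells, the bar is the mean and the whisker 1 SD. Slc26a5 and Ocm are highest in OHCs, Otof and Slc17a8 in IHCs, Gjb6 and Fgfr3 in Deiters' cells, and Myo7a and Pou4f3 in both hair cell types.

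Among the lead genes of OHCs over IHCs were Elovl2, an enzyme that lengthens polyunsaturated fatty acids (467 ± 401 against 1.57 ± 4.63 CPM, ratio -7.51), and Cpt1b, which carries fatty acids into mitochondria (201.8 ± 243.8 against 1.03 ± 2.85, ratio -6.64). Olfm1, a secreted glycoprotein, had 653 ± 516 against 8.35 ± 20.6 CPM (ratio -6.13), and the secreted C1q-like factor C1ql1 had 167.5 ± 227.6 against 0.613 ± 1.39 (ratio -6.71). Zfp365, Megf6, Necab2, Fam20c, Sec16b and Cel followed with ratios from -6.90 to -6.29, and Ighm had -6.43, or -7.17 without IHC_218. The lead genes of IHCs included Gsn, which encodes the actin-severing protein gelsolin (12536 ± 15197 against 36.7 ± 89.2, ratio 8.38), Tpbgl (712 ± 697 against 1.197 ± 4.22, ratio 8.34) and Spock1, a secreted proteoglycan (367 ± 340 against 0.911 ± 2.67, ratio 7.59). The calcium-activated chloride channel gene Ano1 had 285.7 ± 435 against 0.685 ± 2.60 (ratio 7.41). Prkd1, Ppp2r2b, Bmper and Zyx had ratios from 7.59 to 7.22. Cdh18 had 7.21, or 5.72 without IHC_136, Dnajc5b had 7.48, or 8.48 without OHC_204, and Tctex1d1 had 7.21, or 8.13 without OHC_173. A supporting-cell score above the highest OHC score was found in 24 of 34 IHC libraries. How far RNA of supporting cells adds to these lead genes of IHCs was not tested.

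Genes of the sensory hair bundle and of the synapses differed member by member. In the list of mechanotransduction and stereocilia genes, 22 of 30 were higher in OHCs (median -0.81, percentile 0.12), among them Tmie (349 ± 330 against 50.6 ± 94.2, ratio -2.76) and Tmc1 (1021 ± 689 against 315 ± 257, ratio -1.69), which encode parts of the transduction complex. The motor gene Myo3a was among the 8 members higher in IHCs (235.7 ± 225.99 against 69.1 ± 134.2, ratio 1.76). Strc, the gene of stereocilin, had a ratio of -5.13, or -5.78 without IHC_240. Efferent synapse genes were higher in OHCs for 3 of 5 members (median -3.34, percentile 0.01), including the acetylcholine receptor gene Chrna9 (1140 ± 758 against 92.5 ± 149, ratio -3.61) and the calcium-activated potassium channel gene Kcnn2 (261 ± 230.9 against 24.8 ± 54.1, ratio -3.34). Ribbon synapse genes divided evenly, 11 against 11 (median -0.05, percentile 49.2). Their median was 0.125 with the mean of logs, 0.180 with the median over cells and 0.056 after thinning, while some other settings kept the sign. The score of this list was 4.27 ± 1.20 in IHCs and 3.54 ± 0.66 in OHCs. Besides Otof and Slc17a8, the release site gene Rims2 (38.4 ± 75.2 against 0.0266 ± 0.104, ratio 5.26) and the calcium sensor gene Cabp1 (32.9 ± 42.5 against 0.920 ± 2.21, ratio 4.14) were higher in IHCs.

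Calcium handling and general hair cell genes also differed. Of 20 genes for calcium buffering and transport, 13 were higher in IHCs (median 1.199, percentile 99.9). The endoplasmic reticulum pump gene Atp2a3 had 1928 ± 1461 CPM in IHCs and 43.1 ± 127.9 in OHCs (ratio 5.45), whereas the plasma membrane pump gene Atp2b2 had 21.3 ± 36.5 and 718 ± 729 (ratio -5.01). The general hair-cell list was higher in OHCs for 12 of 16 members (median -0.60, percentile 2.33), with Gfi1 at -2.49 and Calb1 at -1.92, while Pou4f3 had -0.29 and Myo7a -0.54 (0.25 for the mean of logs). Potassium channel genes were mixed, with 9 of 16 higher in IHCs (median 0.26, and -0.27 with size factors). Ikzf2, a transcription factor gene of OHCs, had a ratio of -3.39, or -4.00 without IHC_128. Tbx2, a transcription factor gene of IHCs, had 3.49, or 4.86 without OHC_375.

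Genes of supporting cells were higher in IHC than in OHC libraries, for 14 of 16 supporting-cell genes (median 3.53, percentile 100), 13 of 15 Deiters' cell markers (median 2.11, percentile 99.97) and 5 of 5 pillar cell markers (median 3.12, or 3.91 without OHC_179). It also held for 15 of 16 extracellular and tectorial matrix genes (median 3.19, percentile 100), for 9 of 15 genes for gap junctions and ion homeostasis (median 2.73, or 2.07 without IHC_232) and for 10 of 15 Notch genes (median 1.31, or 2.04 without OHC_268). Examples were the gap junction genes Gjb6 (900 ± 803 against 14.8 ± 44.5, ratio 5.83) and Gjb2 (202.04 ± 339.03 against 3.61 ± 10.3, ratio 5.46), the glutamate transporter gene Slc1a3 (427 ± 646 against 3.24 ± 5.71, ratio 6.66) and the matrix gene Sparc (3574 ± 3262 against 141.98 ± 267.8, ratio 4.64). Of 34 IHC libraries, 24 had a supporting-cell score above the highest OHC score of 2.46. Immune markers were higher in IHC libraries for 10 of 11 members (median 2.90, or 2.21 without IHC_227). The largest lead ratio in IHCs, that of the macrophage and neutrophil gene Lyz2, was 10.10, or 8.24 without IHC_227. Libraries IHC_218, IHC_219, IHC_227 and IHC_237 together held 91.4% of the Lyz2 signal of all IHCs.

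The comparison of Deiters' cells with OHCs sets a supporting cell against the sensory cell that rests on it. Deiters' cells had far more transcript of the tectorial membrane protein gene Ceacam16, the gap junction gene Gjb6 and the receptor gene Fgfr3, and OHCs had far more of Slc26a5, of the receptor genes Chrna9 and Chrna10 and of the hair cell transcription factor gene Pou4f3. Ceacam16 (chromosome 7, 19852097 to 19861299) had 58617 ± 35389 CPM in Deiters' cells and 261 ± 519 in OHCs (ratio 7.81). Gjb6 (chromosome 14, 57123303 to 57133611) had 3055 ± 2054 and 14.8 ± 44.5 (ratio 7.60), and Fgfr3 had 1919 ± 1497 and 45.6 ± 170.9 (ratio 5.37, or 6.11 without OHC_269). In OHCs, Slc26a5 had 3879 ± 1849 against 15.0 ± 26.3 CPM (ratio -7.92), Chrna9 had 1140 ± 758 against 2.69 ± 3.57 (ratio -8.27) and Pou4f3 had 1120 ± 783 against 5.71 ± 6.95 (ratio -7.38). All 16 hair-cell genes (median -5.63, percentile 0) and all 10 OHC markers (median -5.58, percentile 0) were higher in OHCs.

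Further lead genes of Deiters' cells were Rbp7, a retinol-binding protein gene (4521 ± 5083 against 16.03 ± 36.97, ratio 8.05), the protease gene Bace2 (6457 ± 2733 against 28.8 ± 77.6, ratio 7.76) and Emid1 (474 ± 627 against 0.460 ± 0.906, ratio 8.35). Odf3l2, Dpp4, Tspan8, Cers2 and Fscn1 had ratios from 8.35 to 7.69, Stmn1 had 7.99, or 8.62 without OHC_253, and Ces1d had 7.57, or 8.62 without OHC_258. On the side of OHCs, the heparan sulfate enzyme gene Hs3st3b1 (598 ± 592 against 0.729 ± 0.784, ratio -8.44) and the actin-binding gene Lmod3 (671 ± 796 against 1.52 ± 2.26, ratio -8.06) led. Mmp23, Dnah8, AI593442, Tuba8 and Ighm had ratios from -7.46 to -7.27. Chrna10 had -7.65, or -8.48 without Deiter_337, and the carbonic anhydrase gene Car7 had -7.38, or -7.99 without Deiter_338.

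The gene groups of each cell's specialised work divided in the same way. Deiters' cell markers were higher in Deiters' cells for 14 of 15 members (median 3.10, percentile 100), supporting-cell genes for 13 of 16 (median 2.98, percentile 100) and pillar cell markers for 5 of 5 (median 3.92, percentile 99.9). Notch genes were higher for 10 of 15 (median 2.15, or 1.23 without Deiter_333), with Hey1 at 6.47 and the ligand gene Jag1 at 6.16. Gap junction and ion homeostasis genes were higher for 12 of 15 (median 2.41, percentile 99.97), for example the potassium channel gene Kcnj16 (1212 ± 1060 against 12.1 ± 22.9, ratio 6.53). Matrix genes were higher for 14 of 16 (median 2.85, percentile 100), with Sparc at 16240 ± 9235 against 141.98 ± 267.8 (ratio 6.83) and Otogl at 924 ± 893 against 5.05 ± 16.1 (ratio 7.26).

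Hair bundle genes were higher in OHCs for 27 of 30 members (median -4.90, percentile 0), among them the tip link gene Cdh23 (1079 ± 865 against 10.03 ± 21.1, ratio -6.61) and Tmc1 (ratio -5.02). Calcium genes were higher in OHCs for 17 of 20 (median -2.42, percentile 0), efferent synapse genes for 4 of 5 (median -5.07, percentile 0.05) and potassium channel genes for 10 of 16 (median -0.75, percentile 15.5). Ribbon synapse genes were higher in OHCs for 18 of 22 (median -1.60, percentile 0.14), with the calcium channel gene Cacna1d at 1110 ± 853 against 40.8 ± 118 (ratio -4.73). With size factors in place of total counts, which raised all genes of Deiters' cells by a median of 1.12, the ribbon synapse median was 0.08. IHC markers did not separate these types (median 0.14, 6 of 11 higher in Deiters' cells), and Otof had a ratio of -2.30 between means but 0.13 between medians over cells. Myo7a had -6.10, or -6.99 without Deiter_337, and Sox2, a supporting-cell transcription factor gene, was near the detection limit at 3.53 ± 11.5 against 0.0843 ± 0.316 CPM (ratio 2.06, or 1.37 without Deiter_331).

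The comparison of Deiters' cells with IHCs asks what separates a supporting cell from the other kind of sensory cell. IHCs had more of nearly all hair-cell and IHC genes, and Deiters' cells had more Fgfr3, Ceacam16, Bace2 and Rbp7, but supporting-cell genes differed less than between Deiters' cells and OHCs. In IHCs, Otof had 3754 ± 2111 against 19.04 ± 33.2 CPM (ratio -7.55), Calb2, which encodes the calcium buffer calretinin, had 9609 ± 5837 against 64.5 ± 115 (ratio -7.20), and Gsn had 12536 ± 15197 against 66.8 ± 132 (ratio -7.53). In Deiters' cells, Fgfr3 had 1919 ± 1497 against 39.2 ± 71.2 (ratio 5.58), Bace2 had 6457 ± 2733 against 400 ± 526 (ratio 4.01) and Ceacam16 had 58617 ± 35389 against 4175 ± 5448 (ratio 3.81). All 11 IHC markers (median -6.44, percentile 0) and 14 of 16 hair-cell genes (median -4.95, percentile 0) were higher in IHCs.

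Other lead genes of IHCs over Deiters' cells were Fcrlb (6674 ± 4523 against 44.6 ± 66.7, ratio -7.19), the lipid transfer gene Pltp (459 ± 530 against 1.92 ± 3.82, ratio -7.30) and Otol1 (313 ± 346 against 1.22 ± 3.43, ratio -7.15). Tctex1d1, Fam65c, Trim45 and Bmper had ratios from -7.49 to -7.16, and Cdh18 had -7.20, or -5.70 without IHC_136. How far RNA of supporting cells other than Deiters' cells adds to these lead genes of IHCs was not tested. Lead genes of Deiters' cells included the corticotropin-releasing hormone receptor gene Crhr1 (439 ± 309 against 9.66 ± 24.2, ratio 5.37), Gstm6 (5.37), Ece1 (4.93) and F2rl1 (4.89). Several of the others changed without a single cell. Umodl1 had 8.99, or 7.02 without Deiter_335, Frem1 had 4.95, or 1.66 without Deiter_331, and Nasp had 4.81, or 0.74 without Deiter_233. Rusc2 had 5.38, or 5.97 without IHC_243, Plekhh1 had 5.15, or 5.88 without IHC_234, Farp1 had 4.93, or 5.72 without IHC_240, and Drc1 had 4.75, or 6.18 without IHC_244.

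Hair bundle genes were higher in IHCs for 26 of 30 members (median -3.49, percentile 0), with Myo3a at -7.02 and Ptprq at -7.11. Ribbon synapse genes were higher in IHCs for 18 of 22 (median -2.40, percentile 0), with Slc17a8 at -6.47, and calcium genes for 18 of 20 (median -2.19, percentile 0), with Pvalb at -6.11. All 5 efferent synapse genes were higher in IHCs (median -2.84, or -3.54 without Deiter_337). Potassium channel genes were mixed, with 9 of 16 higher in IHCs (median -0.94, percentile 4.86), among them Kcna10 (485 ± 401 against 3.97 ± 8.54, ratio -6.61). Deiters' cell markers were higher in Deiters' cells for 9 of 15 (median 1.31, percentile 99.98), supporting-cell genes for 11 of 16 (median 0.66, percentile 99.1) and gap junction and ion homeostasis genes for 11 of 15 (median 1.05, percentile 99.9). In the last list, Kcnj10 had 925 ± 806 against 227.1 ± 316 CPM (ratio 2.02), and the ATP-gated channel gene P2rx2 had 2292 ± 1730 against 599 ± 598 (ratio 1.94). Pillar cell markers (median 0.63, percentile 91.8) and matrix genes (median 0.15, percentile 84.5) lay within the central 95% of random lists, and Notch genes had a median of -0.02, or 0.58 without IHC_211. The choice of average and scaling mattered for these 3 lists, whose medians were 1.02, 1.40 and 1.89 with the median over cells and 2.66, 1.80 and 2.23 with size factors. Gjb6 had a ratio of 1.76, Gjb2 had -0.12 (1.43 with size factors) and Slc1a3 was higher in IHCs at -4.25, or -4.84 without Deiter_205. OHC markers had a median of -1.55, or -0.83 without IHC_240, and the ratio of Slc26a5 itself was -1.44, or 0.10 without that library.

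**Figure D3:**
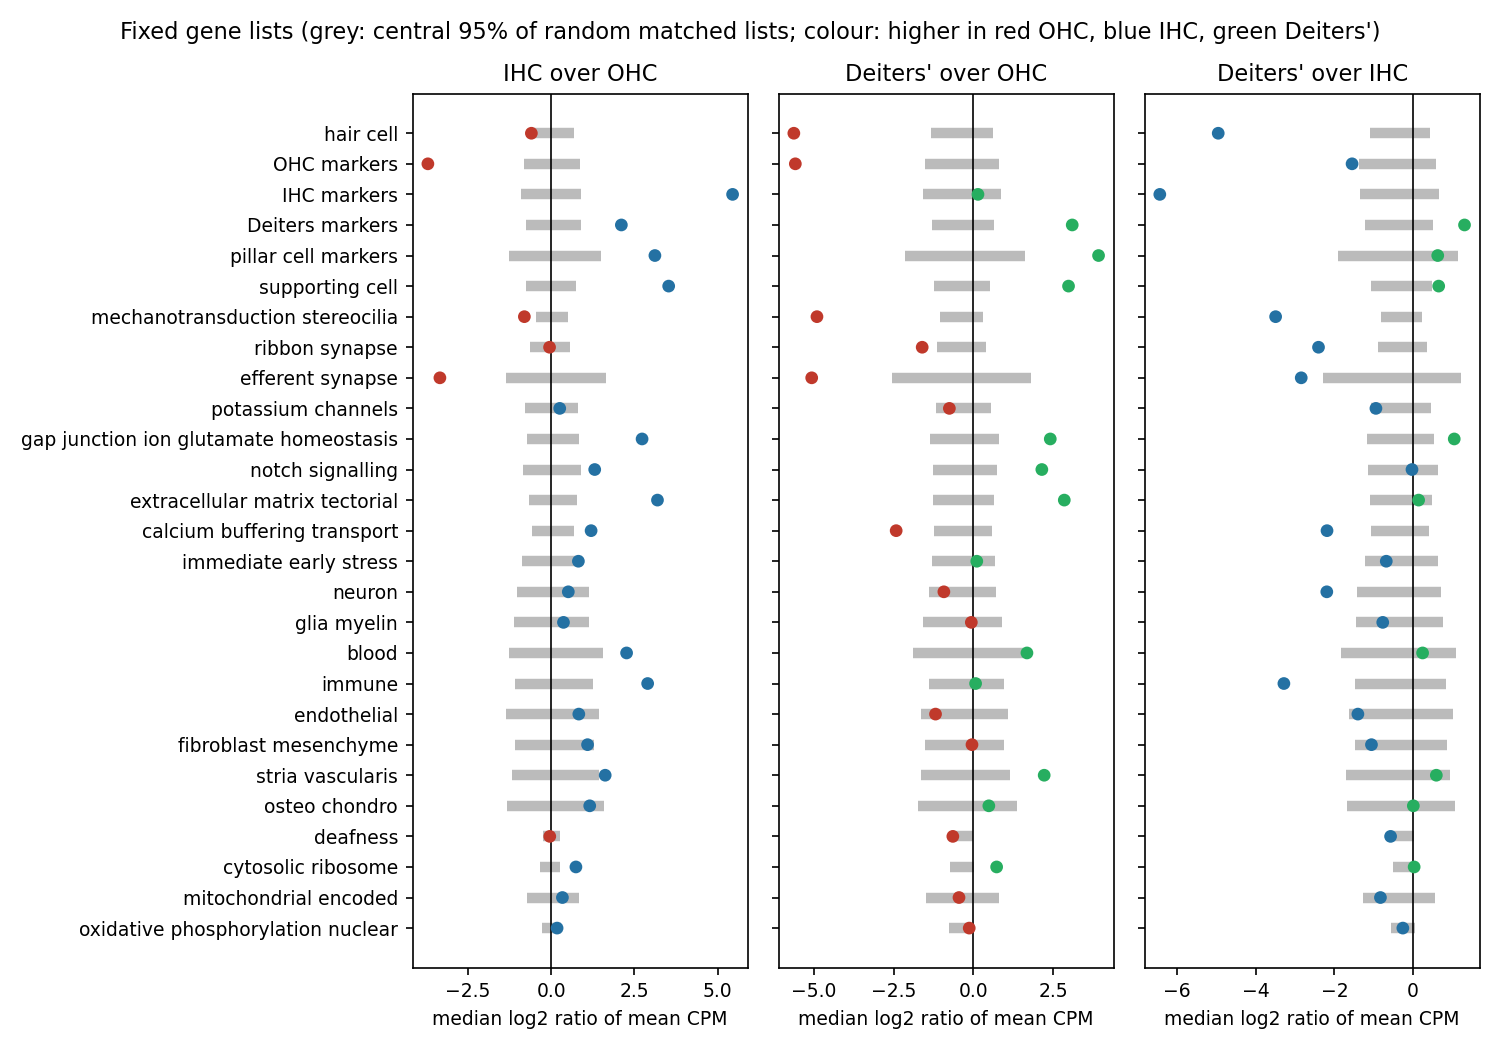
Each point is the median log2 ratio of mean CPM over the members of 1 of 27 fixed gene lists in 1 of 3 comparisons, coloured by the type with the higher level, and the grey bar spans the central 95% of 10000 random matched lists. Hair-cell genes lie at -5.63 in Deiters' cells against OHCs and at -4.95 against IHCs, and supporting-cell genes lie at 3.53 in IHCs against OHCs and at 2.98 in Deiters' cells against OHCs.

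The share of cells with a gene, counted at 100000 counts per cell, separated the types less sharply than the levels did. Slc26a5 had a count in 60 of 60 OHCs (100%, interval 94.0 to 100), 9 of 28 IHCs (32.1%, interval 15.9 to 52.4) and 23 of 37 Deiters' cells (62.2%, interval 44.8 to 77.5). At 10 counts or more the last 2 shares were 0 and 2.70%. Otof had a count in 28 of 28 IHCs (interval 87.7 to 100), 63.3% of OHCs (interval 49.9 to 75.4) and 62.2% of Deiters' cells, and at 10 counts or more in 25% of OHCs and 8.11% of Deiters' cells. Slc17a8 was in 82.1% of IHCs (interval 63.1 to 93.9), 8.33% of OHCs (interval 2.76 to 18.4) and 5.41% of Deiters' cells (interval 0.661 to 18.2). These smaller shares alone do not show that Slc17a8 is more selective, since its IHC level was lower, at 202.5 against 3754 CPM for Otof. Its median level in Deiters' cells was 0.337% of the IHC mean, and that of Otof was 0.263%. Gjb6 was in 37 of 37 Deiters' cells (interval 90.5 to 100), 92.9% of IHCs (interval 76.5 to 99.1) and 35% of OHCs (interval 23.1 to 48.4), and Fgfr3 in 94.6%, 32.1% and 30% in the same order. Prox1, a supporting-cell transcription factor gene, was in 0 of 60 OHCs, which allows a share of up to 5%, in 0 of 28 IHCs, which allows up to 10.7%, and in 5.41% of Deiters' cells. Thinned OHCs, IHCs and Deiters' cells had counts for a median of 4255, 4697 and 4033 genes.

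The expression of genes of hereditary deafness was compared between the types to ask which cells express each gene. Of 132 genes, 108 reached a mean of 10 CPM in at least 1 type and 63 in all 3. OHCs reached it for 87 of them, IHCs for 101 and Deiters' cells for 82. The last count includes hair-cell genes at a small fraction of their hair-cell level, such as Slc26a5 at 15.0 and Otof at 19.04 CPM, and the count of IHCs includes supporting-cell genes that were low in OHCs, such as Gjb6 and Gjb2. Both hair cell types without Deiters' cells expressed 21, including Myo7a, Pou4f3, Ptprq, Strc, Tmie, Whrn and Grxcr1. Of these, Strc, Myo7a and Tmie lay just under the limit in Deiters' cells, at 9.76, 9.28 and 9.19 CPM. In IHC libraries alone, 4 genes reached 10 CPM, namely Slc17a8, Ednrb (112.6 ± 157.5 CPM), Otoa (47.6 ± 96.9) and Tecta (23.4 ± 56.1), the last 2 being known as genes of the tectorial membrane and its attachment. Otoa and Tecta are also members of the supporting-cell list, which was high in the IHC libraries, and their medians over IHCs were 0.826 and 0 CPM. OHCs alone expressed Ush1g (13.4 ± 48.5 CPM, 9.70 without OHC_142 and 9.50 without OHC_143, with 9.28 in IHCs, just under the limit). In Deiters' cells alone, 10 CPM was reached by Grhl2 (41.1 ± 93.6, with 9.987 in IHCs, just under the limit), Kitl (11.6 ± 46.6, or 5.38 without Deiter_335 and 7.38 without Deiter_326), Met (17.4 ± 92.3, or 2.41 without Deiter_331) and Hgf (10.9 ± 65.9, or 0.0745 without Deiter_331). With any single cell left out, OHCs expressed 85 to 87 genes, IHCs 99 to 102 and Deiters' cells 78 to 83, and the genes of 1 type alone numbered 0 to 2, 4 to 5 and 2 to 6.

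Of the 108 expressed deafness genes, 49 were highest in OHCs, 30 in IHCs and 29 in Deiters' cells. OHCs exceeded the second type by 5-fold or more for 6 genes (6 to 8 with any single cell left out), including Slc26a5 (91.5-fold, or 258.6-fold without IHC_240), Strc (36.8-fold, or 59.3-fold without IHC_240), Atp2b2 (33.7-fold), Cdc14a (7.22-fold) and Tmie (6.90-fold). IHCs did so for 5, with Otof 38.4-fold and Slc17a8 137.1-fold above the second type and the others being Ednrb, Otoa and Tecta. Deiters' cells did so for 4 (2 to 6 with any single cell left out), with Ceacam16 14.0-fold above IHCs. The others were Kitl, Met and Hgf, which fell below 10 CPM without 1 library each, Deiter_335 or Deiter_331. Cib2, which encodes a calcium-binding protein of the transduction complex, was the most abundant of these genes in OHCs at 4539 ± 1641 CPM, with 3301 ± 1896 in IHCs and 82.2 ± 101 in Deiters' cells. As a list, deafness genes divided evenly between IHCs and OHCs, 59 against 60 members (median -0.04, percentile 35.7). They were higher in OHCs than in Deiters' cells for 70 of 120 members (median -0.64, percentile 3.94) and higher in IHCs than in Deiters' cells for 78 of 120 (median -0.57, percentile 1.28), but with size factors these medians were 0.53 and 0.72.

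Transcript shares were compared to ask whether the types use different transcripts of the same deafness gene. Triobp, whose proteins bundle actin at the stereocilia rootlets, used its long transcript Triobp-204 (chromosome 15, 78947724 to 79005869) for 40.9% of summed counts in OHCs and 1.78% in IHCs, with means over cells of 40.0% ± 26.8 (SD, n = 60) and 3.70% ± 8.34 (SD, n = 25). The short transcript Triobp-208 (78947724 to 78968842) took 65.7% in Deiters' cells, 18.97% in OHCs and 36.6% in IHCs, with a mean over cells of 66.7% ± 34.1 (SD, n = 32) in Deiters' cells and 20.7% ± 31.3 (SD, n = 60) in OHCs. Ush1c, which encodes the scaffold protein harmonin, used Ush1c-202 (chromosome 7, 46195350 to 46238492) for 55.5% in Deiters' cells and 18.1% in OHCs, with means of 48.3% ± 33.1 (SD, n = 37) and 18.6% ± 15.4 (SD, n = 59). Myo7a-203 took 45.7% of the Myo7a counts in IHCs, 24.8% in OHCs and 7.42% in Deiters' cells, with means over cells of 37.1% ± 31.1 (SD, n = 25) in IHCs and 18.6% ± 28.6 (SD, n = 11) in Deiters' cells, and Myo7a-213 took 1.03% in IHCs and 23.4% in OHCs, with means of 3.39% ± 11.9 (SD, n = 25) and 20.9% ± 32.04 (SD, n = 53). Elmod3-202 took 41.4% in IHCs, 32.7% in Deiters' cells and 0.205% in OHCs, with means of 24.8% ± 35.8 (SD, n = 14), 27.8% ± 40.9 (SD, n = 13) and 0.242% ± 0.765 (SD, n = 10). Cdc14a-201 took 80.5% in OHCs, 70.6% in IHCs and 43.5% in Deiters' cells, with means of 72.2% ± 35.7 (SD, n = 54), 66.4% ± 40.01 (SD, n = 15) and 42.3% ± 41.7 (SD, n = 18).

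Of the eligible deafness genes, 26 of 40 had a transcript whose share differed by at least 10 percentage points between IHCs and OHCs, 29 of 36 between Deiters' cells and OHCs and 24 of 32 between Deiters' cells and IHCs. The median largest difference per gene was 13.6, 20.7 and 16.8 points. These are the largest of each gene's differences, taken from summed counts in which cells with many counts weigh more. No such difference was computed between cells of the same type, so the part owed to the spread between cells is not known. Between the means over cells, 5 of the 24 named differences were larger than the SD between cells, and 23 of 24 had the sign of the summed shares. The exception was Otof-202, whose summed share was 40.9% in IHCs and 72.1% in OHCs, a difference of -31.2 points, but the difference of the means over cells was 3.78 points, with 47.6% ± 20.6 (SD, n = 34) in IHCs and 43.8% ± 38.1 (SD, n = 37) in OHCs. The 2 largest summed differences between Deiters' cells and OHCs were also smaller between means over cells. Gsdme-202 had 16.7% in Deiters' cells and 84.1% in OHCs, but means of 20.04% ± 41.99 and 30.3% ± 46.1 (SD, n = 10 each), and the named Diaph1 transcript had 1.30% and 52.9%, but means of 2.96% ± 9.83 and 15.7% ± 34.2 (SD, n = 11 each). A single transcript took 97.7% of the Slc26a5 counts in OHCs and 76.4% of the Slc17a8 counts in IHCs.

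**Figure D4:**
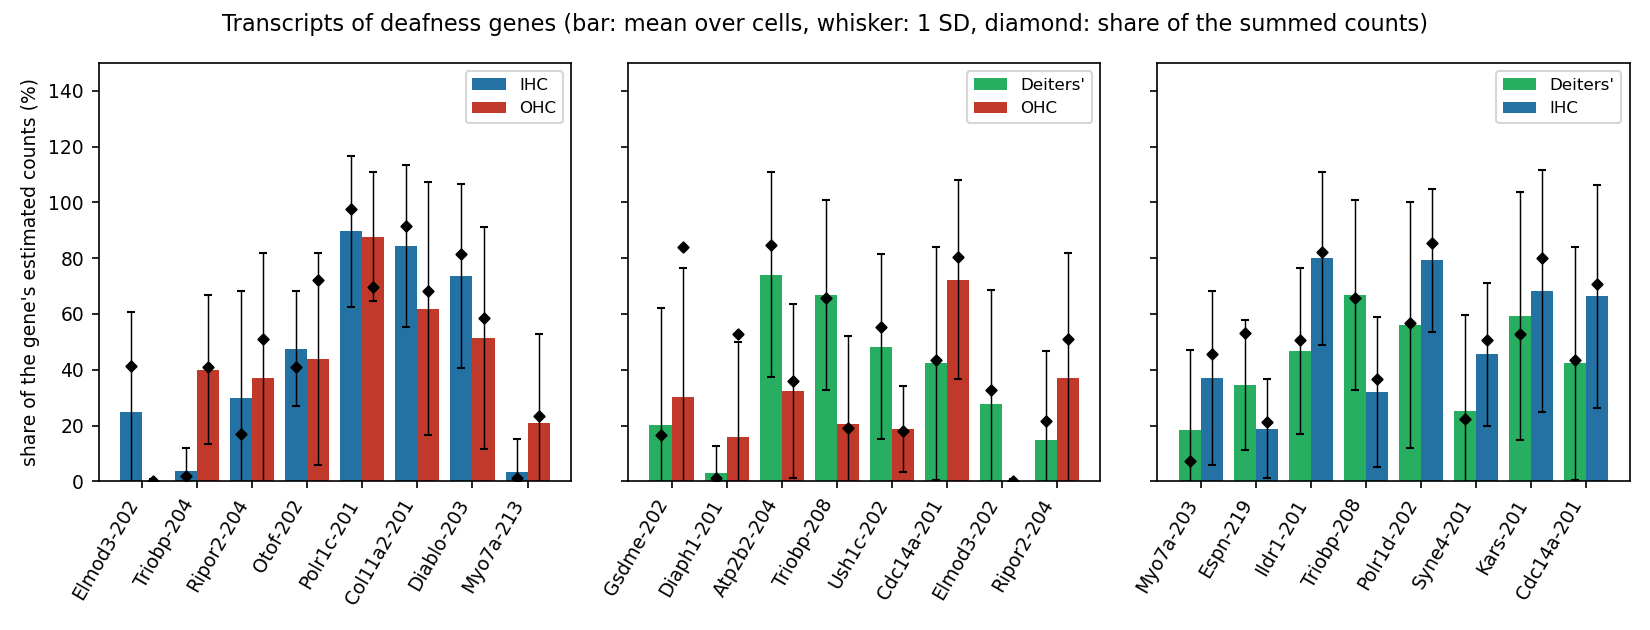
The y axis is the share of a gene's estimated counts (percent) taken by each of the 8 named transcripts per comparison, with bars for the mean over cells with at least 20 counts, whiskers for 1 SD (drawn no lower than 0) and diamonds for the share of the summed counts. Bars and diamonds lie close together for Triobp-204, Triobp-208 and Ush1c-202, and apart for Otof-202, where bars are 47.6% and 43.8% and diamonds 40.9% and 72.1%, and for Gsdme-202 and the Diaph1 transcript in OHCs.

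The Nanopore OHCs were compared with the Illumina cells to ask whether long reads of other OHCs show the same genes. The 12 Nanopore cells had 61016 to 424501 reads each (median 149178.5) and reads of 3427 to 8225 genes (median 6645). Across 11978 genes, their mean profile had a Spearman's rho of 0.706 with OHCs, 0.636 with IHCs and 0.554 with Deiters' cells. These genes had a mean above 0 in Nanopore cells and in Illumina OHCs, with no such demand on the other 2 types. That choice and the larger number of OHCs may favour the OHC value, and their part was not tested. Ocm had 113 ± 33.7 reads per 10000 (SD, n = 12) and Slc26a5 27.4 ± 14.4, which placed them 5 and 11 among all genes in Nanopore cells and 2 and 6 in Illumina OHCs. The first 3 Nanopore genes, CT010467.1, Gm42418 and AY036118, overlap each other on chromosome 17 (39846353 to 39848827) and had 671 to 689 reads per 10000. Reads in at least 6 of the 12 cells were present for 9 of 10 OHC markers, 14 of 16 hair-cell genes, 2 of 11 IHC markers, 5 of 16 supporting-cell genes, 2 of 15 Deiters' cell markers, 4 of 6 blood genes and 0 of 13 immune genes. Slc17a8, Tbx2, Dnajc5b, Fgfr3 and Sox2 had no read in any of the 12 cells.

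The deposited long-read isoform table lists 14824 isoforms at 6080 loci, of which 3149 loci have 1 isoform. Isoforms were listed at loci that hold 58 deafness genes, with a median of 3 per locus. An isoform at a shared locus need not belong to the deafness gene. The leading isoform at the Otoa locus of 8 genes (chromosome 7, 121034551 to 121076845) lies outside Otoa, which starts at 121081650. The counts below are per locus, which can hold several genes, and cover only the reads listed under an isoform. For Slc26a5 these are a small part of its reads, since the gene had 27.4 reads per 10000 in cells of 61016 to 424501 reads. Tmprss3 had the most, 30 isoforms, of which 22 had 2 or more reads. Only its leading isoform took 10% or more of its reads, with 41.5%. The annotation has 4 Tmprss3 transcripts, and whether the listed isoforms are further transcripts was not tested. Wbp2 had 23 isoforms from 359 reads at a locus shared by 4 genes, Triobp 22 from 187 reads at a locus shared by 2 genes and Slc26a5 18 from 197 reads. Reads in at least 6 of the 12 cells were present for 1 of the 30 Tmprss3 isoforms, 7 of the 23 at the Wbp2 locus, 2 of the 22 of Triobp and 3 of the 18 of Slc26a5. The leading Slc26a5 isoform (chromosome 5, 21809577 to 21865614) took 46.7% of its 197 listed reads. Cabp2 had 14 isoforms, Cldn14 had 13 and Smpx had 12, and Eps8l2 had 14 at a locus shared by 2 genes and 1 at another. Ocm had 13 isoforms from 8709 reads at a locus shared by 3 genes, of which the leading one took 92.1%, and Pou4f3 and Myo7a had 11 isoforms each, from 480 and 36 reads. Gjb6 had 3 isoforms from 96 reads, Ikzf2 had 2 from 10 reads at a locus shared by 4 genes, Tmc1 had 1 from 10 reads and Otof had 1 from 7 reads, and so few reads limit how many isoforms can be seen.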

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

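All tests in this part were chosen only after the results were seen. The deposited window files of the Nanopore cells, which no comparison above uses, hold 12649 splice site windows and 18343 transcript end windows that contain no annotated site and whose names end in a number. These were singled out as a signal in data outside the gene and isoform tables, with a limit of 3 windows for a count of 0. They are 96.5% of 13111 splice site windows and 96.0% of 19101 transcript end windows of this kind, with median numbers of 0.206 and 0.218, whose meaning the files do not give. Windows whose names end in A contained an annotated site in 99.9% of 469806 splice sites and 98.4% of 199683 transcript ends. No explanation of the unannotated windows was tested.

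Supporting-cell genes were high in IHC libraries, and 24 of 34 IHC libraries scored above the highest OHC library, which argues against a few libraries as the source. RNA of Deiters' cells as the only source is argued against by unequal levels, tested on genes chosen without IHC values (under 5% of the Deiters' level in OHCs). The 6 supporting-cell genes with at least 20 CPM in Deiters' cells had 21.9% or more of their Deiters' level in IHCs, with a median of 52.9%. Of 28 other genes with at least 1000 CPM in Deiters' cells, 13 (46.43%) lay more than 3-fold below that median, under 17.6%, and 8 more than 3-fold below the lowest, under 7.31%, among them Ceacam16 at 7.12% and Fgfr3 at 2.04%. Reads exchanged between IHC and Deiters' libraries during sequencing are argued against because Deiters' libraries held 10 IHC markers at a median of 0.2413% of the IHC level. Supporting cells of another kind that adhered to the IHCs, with or without RNA of Deiters' cells, and expression by the IHCs themselves were not tested and stay open.

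Hair-cell genes were present at a low level in Deiters' libraries, and most had the same small percentage of their hair-cell level. Of 44 genes, 37 (84.09%) lay within 3-fold of a median of 0.3025% of the hair-cell mean over all Deiters' cells. For them, 1 background source, such as RNA freed during dissociation or reads exchanged between libraries, has the values it needs and may account for most of these 37. In 19 of the Deiters' cells, 7 genes lay more than 3-fold above the median. In the other 18 cells, Ush1c (44.8%), Triobp (18.4%) and Smpx (13.44%) of these 7 lay above every gene not chosen, the highest of which was Eps8l2 at 7.885%, which argues against the same background for these 3. For them, expression in Deiters' cells themselves is a hypothesis, and other sources were not tested. Myo6 was at 5.296% in these 18 cells, and Cib2, Sall3 and Rdx were at 0.576, 0.548 and 0.208%. For these 4 genes a gene's own level and the background cannot be told apart. For Cib2, Sall3 and Rdx the 2 sets of cells differ, with Sall3 at 19.8% in the 19 cells. Myo6 lay more than 3-fold above 0.3025% in both sets, with 1.97% in the 19 cells, but below Eps8l2, a gene not chosen. Eps8l2 and Lbh, both among the 37, had 0.458 and 0.596% in the 19 cells but 7.885 and 2.07% in the 18, so the background alone may not account for them.

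Libraries IHC_240 to IHC_244 had 11187 to 16604 counts each and resembled one another. Reads of 1 library deposited 5 times are argued against by the shares of abundant genes. Of 13 genes with a mean of at least 50 counts, 4 (30.77%) differed more than 2-fold between the 5 libraries, with Ceacam16 at 8.34-fold. Repeated preparations of 1 cell were not tested. At 10000 counts, their pairs had a median correlation across genes of 0.6619, above the 95th percentile of 0.5805 and the highest value of 0.6246 among 406 pairs of other IHC libraries, and they had 3661 to 3999 genes against a median of 2838. Reads of several libraries mixed into these 5 may have added to the likeness, which the correlation measures but does not explain. A mixture of the same composition in all 5 as the only source is argued against by the same differences in abundant genes. Mixtures of differing composition as the only source, mixed reads beside each library's own reads, and a biological likeness of 5 cells were not tested and stay open.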

How the results depend on the processing

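The values without the 5 shallowest IHC libraries, without 4 immune-rich IHC libraries and without OHC_139 were chosen after seeing the data. Of the alternative values of results that answer a comparison, 76.1% stayed within the spread between cells or within 1.5 times a count, 23.9% moved further and 0 reversed. Reversed means a change of sign from a reported value of at least 1 log2, or 1 percentage point for transcripts. Counts and shares of cells are among the results that answer a comparison. They cannot change sign, so for them the absence of reversals was fixed in advance. Of 3501 values for single genes, lists and transcripts, 94.5% stayed, 5.08% moved and 13 reversed. A further 82 values of single genes and lists changed sign from a reported value below 1 log2. Over 19 settings, the medians of the marker lists given here kept their sign. In IHCs against OHCs they ran from -6.55 to -3.36 for OHC markers, 4.21 to 7.30 for IHC markers and 1.83 to 6.45 for supporting-cell genes. In Deiters' cells they ran from -6.53 to -4.49 against OHCs and -5.86 to -3.01 against IHCs for hair-cell genes, and from 1.72 to 6.80 and 0.35 to 1.99 for supporting-cell genes. The planned removal of cells with too few genes left out 0 cells and gives no value. Low depth limits the 7 cells under 100000 counts, which the shares of cells leave out.

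The lead genes depended on the averaging and on the pseudocount, among other choices. Of 24 in IHCs against OHCs, 7 remained with the mean of logs, 7 with the median over cells, 14 with TPM, 15 with a pseudocount of 0.1 and 8 with 10. Of 24 in Deiters' cells against OHCs, 10 remained with the mean of logs, 10 with the median, 7 with a pseudocount of 0.1 and 12 with 10. Of 24 in Deiters' cells against IHCs, 14 remained with summed counts, 6 with the mean of logs, 9 with the median, 12 with TPM, 15 with a pseudocount of 0.1, 9 with 10, 14 without cells under 100000 counts, 12 after thinning and 15 without the 5 shallowest IHCs. The cause was not tested.

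With the median over cells, IHCs against OHCs gave -6.55 for OHC markers, 7.30 for IHC markers, 6.45 for supporting-cell genes and a reversed -0.61 for stria vascularis genes (1.62 between means). A pseudocount of 10 gave 4.21 for IHC markers. In Deiters' cells against OHCs, the hair-cell median was -4.49 with a pseudocount of 10. Supporting-cell genes had 1.72 with the mean of logs, 6.80 with the median over cells, 4.79 with size factors, 3.97 with a pseudocount of 0.1 and 2.03 with 10. Otof reversed to 0.13 with the median over cells, and ribbon synapse genes to 0.0773 with size factors. In Deiters' cells against IHCs, the hair-cell median was -3.86 with the mean of logs, -3.77 with size factors, -4.02 with TPM and -3.01 with a pseudocount of 10. With size factors, Tbx2 reversed from -2.60 to 0.19 and fibroblast genes from -1.05 to 0.50. Without Deiter_205, and with total counts, Tbx2 had -6.03. The shift of all genes that size factors bring, above 1 log2 in both Deiters' comparisons, accounts for part of these changes, and the rest was not tested. Slc26a5 (-1.44) reversed to 0.62 with summed counts, 0.90 with the mean of logs, 1.88 with the median, 0.83 without cells under 100000 counts and 0.97 after thinning. With each cell left out it ran from -1.85 to 0.10, the highest without IHC_240, a library of few counts.

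Shares of cells depended on depth and on the count required. Without thinning, Slc26a5 was in 73.5% of IHCs and 97.3% of Deiters' cells, Otof in 90.2% of OHCs and 100% of Deiters' cells and Gjb6 in 77.0% of OHCs. At 10 counts or more, Slc26a5 was in 0 and 2.70%, Otof in 25% and 8.11%, and Gjb6 in 5% of OHCs and 75% of IHCs. The markers of 30 IHCs, in place of 13, went with their label without z-scaling. At 50 CPM, OHCs expressed 60, IHCs 67 and Deiters' cells 43 deafness genes, with 23 in all 3 types in place of 63. Genes of 1 type alone were then 11 in OHCs, 7 in IHCs and 5 in Deiters' cells, in place of 1, 4 and 4. Of the 8 named transcripts, 5 remained with the mean over cells and 4 with TPM in IHCs against OHCs, 5 and 3 in Deiters' cells against OHCs and 4 and 4 in Deiters' cells against IHCs. The difference of Otof-202 reversed from -31.2 to 3.78 and 2.83 points. The rho of the Nanopore profile fell to 0.609 with OHCs when shares replaced means, and to 0.471 with Deiters' cells for genes at 10 or more in either table. The cause was not tested.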

Other observations

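The values of single libraries in this part were looked up only after the list results were seen. Genes for cytosolic ribosomes were lower in OHCs than in the other types. They were higher in IHCs for 72 of 84 members (median 0.74, percentile 100), with Rpl22l1 at 50.2 ± 82.2 against 10.2 ± 26.5 CPM, and higher in Deiters' cells for 74 of 84 (median 0.73, percentile 100), with Rpl11 at 142.4 ± 216.7 against 37.9 ± 60.6. Between Deiters' cells and IHCs they divided 46 to 38 (median 0.03). Genes encoded by mitochondria were higher in hair cells than in Deiters' cells for 12 of 13 members in both comparisons (median -0.45, percentile 41.3, against OHCs and -0.83, percentile 11.9, against IHCs), with mt-Nd5 at 924 ± 980 CPM in IHCs, 421 ± 386 in OHCs and 418 ± 412 in Deiters' cells, but with size factors these medians were 1.31 and 0.88. Between IHCs and OHCs, 9 of 13 were higher in IHCs (median 0.34, percentile 78.1). Nuclear genes of oxidative phosphorylation were higher in IHCs than in OHCs for 55 of 80 (median 0.18, percentile 88.8, and -0.04 with TPM). They were higher in OHCs than in Deiters' cells for 46 of 80 (median -0.13, percentile 85.7) and higher in IHCs than in Deiters' cells for 60 of 80 (median -0.26, percentile 43.75), and 1.39 and 1.32 with size factors. In all 3 comparisons, the medians of these last 2 lists lay within the central 95% of random lists. Ndufs1, a subunit gene of respiratory complex I, had 246.2 ± 304 CPM in OHCs, 251.7 ± 325.6 in IHCs and 40.3 ± 79.2 in Deiters' cells.

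Immediate early and stress genes were mixed. In IHCs against OHCs, 9 of 15 were higher in IHCs (median 0.82, or 0.23 without IHC_240), with the transcription factor gene Nr4a1 at 31.6 ± 80.4 against 0.0681 ± 0.240 CPM. In Deiters' cells the median was 0.11 against OHCs and -0.68 against IHCs, or -1.27 without Deiter_228. Dusp1, a phosphatase gene, had 228.1 ± 365 CPM in Deiters' cells, 36.98 ± 86.0 in OHCs and 9.46 ± 23.2 in IHCs. Neuron markers were higher in IHCs than in Deiters' cells for 7 of 10 (median -2.19, percentile 0.05), with the neurofilament gene Nefm at 38.4 ± 88.3 against 1.33 ± 4.19 CPM. They had a median of 0.51 in IHCs against OHCs and of -0.92 in Deiters' cells against OHCs, or -1.67 without Deiter_331.

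For markers of other cells that a pipette could carry, several medians changed when a single library was left out. Immune markers had a median of 0.07 in Deiters' cells against OHCs and of -3.28 in Deiters' cells against IHCs, or -2.34 without IHC_227. Libraries IHC_218, IHC_219, IHC_227 and IHC_237 held 66.3% of the S100a8 signal and 79.4% of the S100a9 signal of all IHCs, and IHC_227 had 29170 CPM of Lyz2. Blood genes had a median of 2.27 in IHCs against OHCs, or 1.30 without IHC_239, of 1.68 in Deiters' cells against OHCs, or 0.89 without Deiter_210, and of 0.25 in Deiters' cells against IHCs, or -1.27 without Deiter_210. The highest blood scores were 8.81 in Deiter_210 and 8.14 in IHC_239, whose hair-cell scores were 3.003 and 7.25, against 1.74 in OHC_139.

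Glia and myelin markers had medians of 0.37 in IHCs against OHCs (1.19 without OHC_137 and -0.27 without cells whose raw file was truncated), -0.06 in Deiters' cells against OHCs (1.10 with size factors and 6.97 with the median over cells) and -0.77 in Deiters' cells against IHCs (0.27 and 1.73). Endothelial markers had 0.83 in IHCs against OHCs (0.08 without IHC_234 and -1 after thinning), -1.19 in Deiters' cells against OHCs and -1.40 in Deiters' cells against IHCs (-0.59 without IHC_234). Fibroblast markers had 1.09 in IHCs against OHCs (1.73 without OHC_201), -0.04 in Deiters' cells against OHCs (1.19 with size factors) and -1.05 in Deiters' cells against IHCs (0.50 with size factors and -1.75 without Deiter_331). Markers of the stria vascularis, the tissue of the cochlea's lateral wall that secretes endolymph, had 1.62 in IHCs against OHCs (0.85 without IHC_218 and -0.61 with the median over cells), 2.22 in Deiters' cells against OHCs (1.43 without Deiter_215) and 0.60 in Deiters' cells against IHCs. Bone and cartilage markers had 1.16 in IHCs against OHCs (0.55 without IHC_239 and 1.80 without OHC_167), 0.48 in Deiters' cells against OHCs and 0.01 in Deiters' cells against IHCs (-1.07 without Deiter_233 and -0.77 with TPM).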
